A study of Mus musculus with 16 samples.

How the data were processed

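Kidney tissue was measured by MeRIP-seq, with an input and an m6A-selected library per sample. Per the labels' protocols, poly(A) RNA was purified from total RNA, fragmented, in part incubated with an m6A antibody, and made into dual-index libraries with dUTP marking of the second strand for paired-end sequencing on an Illumina NovaSeq. The authors' table gave FPKM per gene for the input libraries, per the file headers and a key to the columns, and gene symbols, positions and KEGG pathway names beside them. Deposited FPKM values were used as they stood, 1 value per gene and library, with replicates kept separate. Per the submitters' processing notes, fastp, FastQC, HISAT2, StringTie and HOMER were used; their roles, versions and settings, the annotation and the genome build are not given in the sources used here. Gene positions are those of the authors' table. A start or end lay within 10 kb of the one in RefSeq's table for GRCm38.p6 for 22967 of 23050 shared symbols, and no coordinates were taken from that table. The m6A-selected libraries and m6A peaks were not analysed here, so the comparisons fixed for them (m6A-selected FA against control, selected over input, and selected against input) were not made.

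FPKM divide by transcript length and library total, so they carry no depth. Low values, under 0.3 FPKM, were searched for steps that whole reads would leave in the ratio of a gene's values between libraries; no more than 16 of 2677 ratios fell in 1 bin of 0.01 on the log2 scale. The depth is therefore unknown, and no count-based test was run. Listed zeros can be failed estimates, and a gene with zeros is described by its library values.

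Groups came from the library names in the labels: 4 control and 4 FA input libraries. Values were transformed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 4 libraries were tested, 13064 in all. FA was compared with control by limma (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Of the 35 gene lists, the 33 with at least 3 members tested were put through camera at its preset correlation of 0.01 with Benjamini-Hochberg adjustment over these lists, through camera again with an estimated correlation, and through fry. Of 614 distinct list genes, 4 were found under another RefSeq name and 11 (Alox15, Camp, Cyp11a1, Cyp11b1, Cyp11b2, Cyp21a1, Fgf21, Il19, Lep, Ngp and Tat) were not measured here; Ctgf and Ccn2 name the same gene, which was counted once. Hmox1 and Mettl3 also had an exact two-sided permutation test. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

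Tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took Hmox1 and Mettl3; up to 4 members per list, the 3 with the largest absolute difference among those past the threshold and the most abundant; any member of the m6A, heme and iron, ferroptosis and folate lists; and the 10 largest rises and falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 FPKM, without predicted genes and pseudogenes. Genes outside the rule are said to be named after their values were seen, and a few genes that the rule or the text could have named are not reported here.

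Alternatives were run singly against the comparison above: a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, the same total FPKM, the same 75th percentile, quantile normalization, array weights, eBayes without a trend and with robust estimation (both changed together), the replicate number as a block, and each library left out in turn. Another 2 were chosen after seeing the data: the same total without the 50 most abundant genes, and leaving out each library with the genes tested held at those of the full comparison. The last was chosen after the leave-one-out counts had been seen, since leaving out an FA library removes genes that only FA libraries list above the minimum; the leave-one-out results fixed beforehand apply the filter anew. A value whose sign changed under an alternative while neither side passed the threshold was not counted as a reversal. The procedure was tested on simulated data drawn from the control means and the fitted spread of each gene, with 200 genes changed in each of 5 runs over 12258 to 12282 genes. It recovered 16% of genes changed by 0.25, 87.2% of those changed by 0.5 and 100% of those changed by 1 or 2 on the log2 scale. Of 794 simulated calls, 36 (4.53%) were false, and 22 of 500 random lists had a camera p under 0.05. Simulated genes were drawn independently of each other, and only genes well above the floor in controls were changed. These rates therefore do not carry over to lists whose members move together, nor to a shift shared by many genes.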

Results

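The series compared kidneys of C57BL mice that had received an intraperitoneal injection of folic acid (FA) with kidneys of control mice. A high dose of folic acid injures the renal tubule and is widely used as a mouse model of acute kidney injury. For these mice the labels give no dose, time after injection, vehicle, sex or age. The study used MeRIP-seq, in which fragmented poly(A) RNA is sequenced both before (input) and after pull-down with an antibody against N6-methyladenosine (m6A), a base modification of mRNA. Expression values of the input libraries, 4 from control and 4 from FA kidneys, were used, and these measure mRNA level. The m6A-selected libraries were not analysed here, so no methylation level is reported. Values were FPKM (fragments scaled to transcript length and to the number of mapped fragments), as the authors gave them for 28005 genes. They summed to between 289994 and 308385 per library. Read counts could not be recovered from these values, so the depth of each library is unknown and no counting interval is given. Nothing in the labels says whether the 4 libraries of a group came from separate animals, so p-values measure the spread between these libraries.

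Control and FA libraries formed separate groups. Pearson's r of log2 values across genes, which are not independent replicates, was 0.985 to 0.990 within groups and 0.908 to 0.934 between them. The principal component that separated the groups held 79.6% of the variance, and FA replicate 3 lay furthest from the controls along it. Genes listed at 1 FPKM or more numbered 12382.5 ± 85.2 (SD, n = 4) per control library and 13149.8 ± 107 per FA library. Kap, the kidney androgen-regulated protein of the proximal tubule and the most abundant transcript, took 12.6% ± 0.944 (SD, n = 4) of the summed FPKM in controls and 6.13% ± 1.35 in FA kidneys. The share was lowest in FA replicate 3, at 4.22%. Because FPKM are relative, such a shift in 1 transcript moves the values of all others.

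The comparison of FA with control kidneys asked how the kidney transcriptome differed after the injection. Higher in FA kidneys were tubular injury markers and transcripts of cytokines, complement, extracellular matrix, macrophages and dividing cells. The last 4 of these groups were not called with an estimated correlation within the list. Kidney tissue was measured in bulk, so which cells held a transcript was not tested. Lower were transcripts of each listed tubule segment from the proximal tubule to the collecting duct (the thin limbs had no list). So were those of endothelium and red cells, and of fatty acid oxidation, mitochondrial respiration and amino acid catabolism. Of these groups, only injury markers, cytokines and the proximal tubule kept their call when the correlation within each list was estimated. By limma with Benjamini-Hochberg adjustment, 7787 of 13064 genes tested passed an adjusted p of 0.05, with 5487 higher and 2300 lower in FA kidneys. Of these, 917 were at least 2-fold higher and 217 at least 2-fold lower, against 1366 and 320 with a pseudocount of 0.1. The split depended on the scaling: under quantile normalization 3364 genes were higher and 4265 lower, and with libraries brought to the same 75th percentile 3614 were higher and 3855 lower. The counts at least 2-fold higher and lower were then 621 and 333, and 704 and 339. With the deposited scaling the median gene was 0.15 higher in FA kidneys on the log2 scale, and medians of gene lists are given relative to that shift. Differences are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Levels are given as mean ± SD (n = 4 per group), the control group before the FA group, and log2 differences as FA minus control ± SE.

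**Figure D1:**
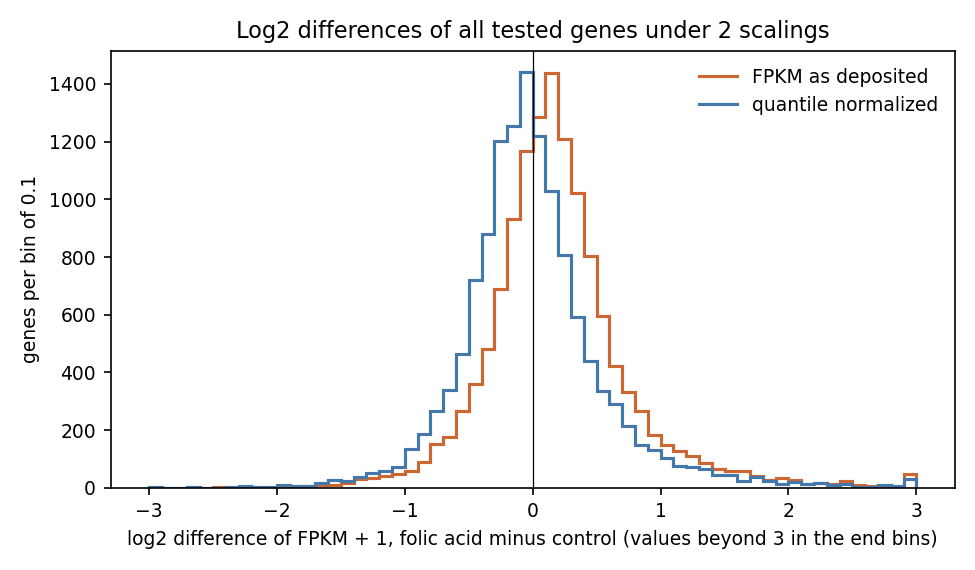
Number of genes (vertical axis) per bin of 0.1 in the log2 difference of FPKM + 1, folic acid minus control (horizontal axis), for 13064 genes with the values as deposited (orange) and after quantile normalization (blue). The median gene lies at 0.15 with deposited values and at -0.049 after quantile normalization, and genes beyond 3 in either direction are placed in the end bins.

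Genes were grouped into 35 fixed lists of cell types, segments and pathways, of which 33 had at least 3 members tested. Camera, which compares a list with all other genes, called 10 lists higher and 12 lower in FA kidneys. With a correlation estimated for each list, the calls for tubular injury markers, cytokines and proximal tubule transcripts held, and the others were lost. Lists share members, among them Spp1 (injury and cytokine lists) and Atf3 (injury, ATF4 and immediate early lists), so their calls are not independent of each other. Counts of members were the same when adjusted over the list alone, except for 5 lists where that count is also given.

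**Figure D2:**
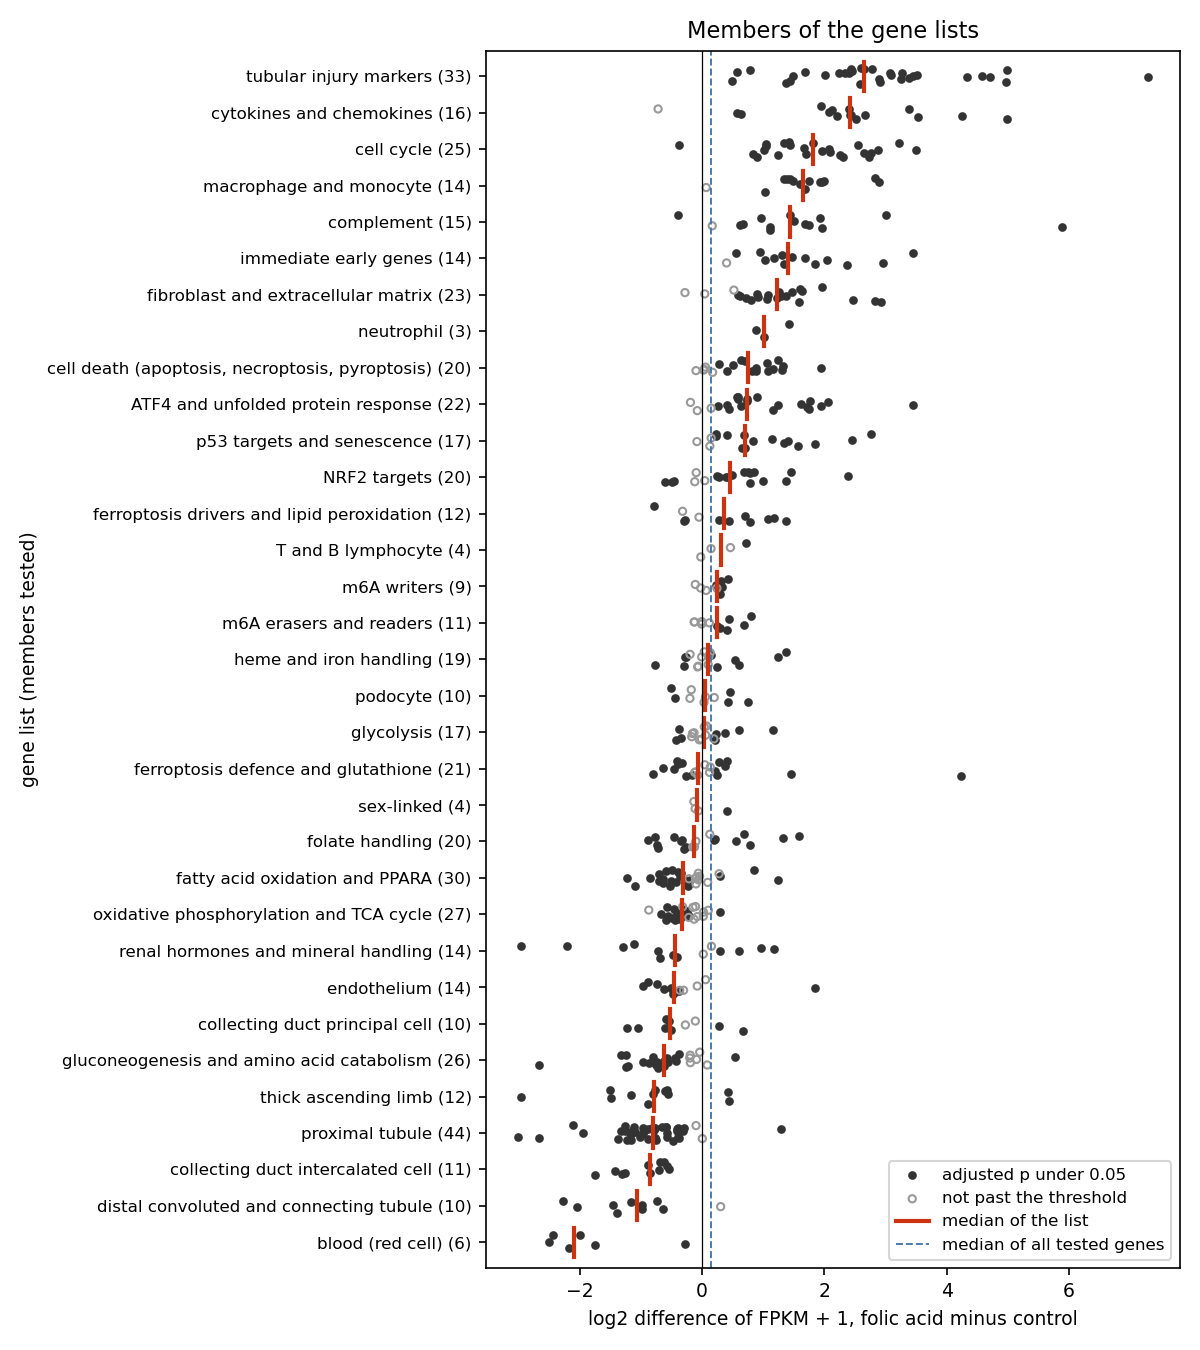
Log2 difference of FPKM + 1, folic acid minus control (horizontal axis), of each tested member of the 33 gene lists (vertical axis, number tested in brackets). Filled points had a limma adjusted p under 0.05 and open points did not; red bars are list medians, and the dashed line is the median of all tested genes, 0.15. Median differences ran from -2.09 for red cell transcripts to 2.64 for tubular injury markers, both with the same sign under every scaling run.

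Heme oxygenase 1 and the m6A methyltransferase METTL3 are the genes named in the title of the series. Hmox1, whose product breaks down heme and releases iron, rose from 17.0 ± 2.96 to 45.3 ± 5.46 FPKM (log2 difference 1.37 ± 0.13), with limma's adjusted p = 1.5e-05. Its values were 13.2 to 19.6 FPKM in control and 38.7 to 51.1 FPKM in FA libraries, so the groups did not overlap. Mettl3, the catalytic subunit of the m6A writer complex, rose from 3.53 ± 0.167 to 4.58 ± 0.249 FPKM (log2 difference 0.30 ± 0.060), with limma's adjusted p = 0.0019. Relative to the shift of the median gene, the differences were 1.22 for Hmox1 and 0.15 for Mettl3. An exact two-sided permutation test over the 70 splits of the 8 libraries gave p = 0.0286 for each gene, the smallest value that 4 against 4 libraries can give. The Hmox1 call held under every scaling, while Mettl3 missed the threshold after quantile normalization (difference 0.091, limma adjusted p = 0.19) and at the same 75th percentile (0.14, limma adjusted p = 0.068). The authors' table places Hmox1 on chromosome 8 from 75093621 to 75100589 and Mettl3 on chromosome 14 from 52294841 to 52305128, in coordinates whose genome build is not given in the sources used here.

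Transcripts of other m6A writers changed little beyond the shift of all genes, and those of m6A-binding proteins went further for single genes. Of 9 m6A writer genes, 5 rose, 0 fell and 4 did not pass the test. The genes that rose were Rbm15b (0.43 ± 0.061), Wtap (0.33 ± 0.063), Cbll1 (0.31 ± 0.074), Mettl3 and Mettl14 (0.22 ± 0.065), differences given before the shift of all genes is taken off. After quantile normalization 1 writer gene was higher and 2 were lower, and the difference of Mettl14 changed sign to -0.0029. Wtap, Cbll1, Mettl3 and Mettl14 did not pass the test there or at the same 75th percentile. Among 11 genes for demethylases and m6A-binding proteins, 6 rose and 0 fell, against 4 higher and 4 lower after quantile normalization. Igf2bp2, which encodes an m6A-binding protein, rose from 0.654 ± 0.208 to 1.87 ± 0.192 FPKM (log2 difference 0.80 ± 0.099). Hnrnpc rose from 23.6 ± 0.240 to 38.5 ± 3.59 FPKM (log2 difference 0.68 ± 0.065). The demethylase genes Fto (-0.13 ± 0.057) and Alkbh5 (-0.0039 ± 0.051) did not pass the test, but both were lower after quantile normalization (limma adjusted p = 7.6e-04 and 0.014) and at the same 75th percentile (0.0016 and 0.0093). Fto was also lower at the same total without the 50 most abundant genes (limma adjusted p = 0.014). Neither list was called by camera, with a camera adjusted p of 0.43 for each. Fry, which does not compare a list with other genes, called both lists higher (fry adjusted p = 0.0020 and 0.0011). Their medians were 0.097 and 0.091 above that of all genes.

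Every one of the 33 tubular injury markers rose, with a median 2.497 above that of all genes (camera adjusted p = 9.2e-16, and adjusted p = 0.025 with an estimated correlation). Havcr1, which encodes kidney injury molecule 1, rose from 1.45 ± 0.825 to 368 ± 36.4 FPKM (log2 difference 7.30 ± 0.21). Spp1, which encodes osteopontin, rose from 291 ± 56.8 to 9163 ± 1326 FPKM (log2 difference 4.98 ± 0.14). Lcn2, which encodes the neutrophil gelatinase-associated lipocalin, rose from 1.38 ± 0.783 to 71.2 ± 7.04 FPKM (log2 difference 4.98 ± 0.20). Among all genes chosen by the rule for large changes, the 10 with the largest rise also held C3 (5.89 ± 0.18), the adhesion molecule Vcam1 (4.58 ± 0.10), the ubiquitin-like Ubd (4.53 ± 0.20), Serpina10 (4.47 ± 0.13) and the diamine oxidase gene Aoc1 (4.40 ± 0.19). The keratin Krt20 was listed at 0 to 0.136 FPKM in controls and at 20.1 to 32.4 FPKM in FA libraries. Sprr2f was listed at 0 in all 4 control libraries and at 20.01 to 30.4 FPKM in FA libraries. The 10 with the largest fall were Cyp2d12 (-3.10 ± 0.24), Slc22a7 (-3.01 ± 0.65), Egf (-2.96 ± 0.29), Hpd (-2.67 ± 0.18), Hbb-bs (-2.51 ± 0.27), Nccrp1 (-2.49 ± 0.40), Hba-a2 (-2.44 ± 0.24), Pvalb (-2.27 ± 0.22), Cyp2d9 (-2.26 ± 0.19) and Dnase1 (-2.21 ± 0.19). Cyp2d9 and Cyp2d12, like the globin genes, have close copies among which reads can be split, so their single values are uncertain.

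**Figure D3:**
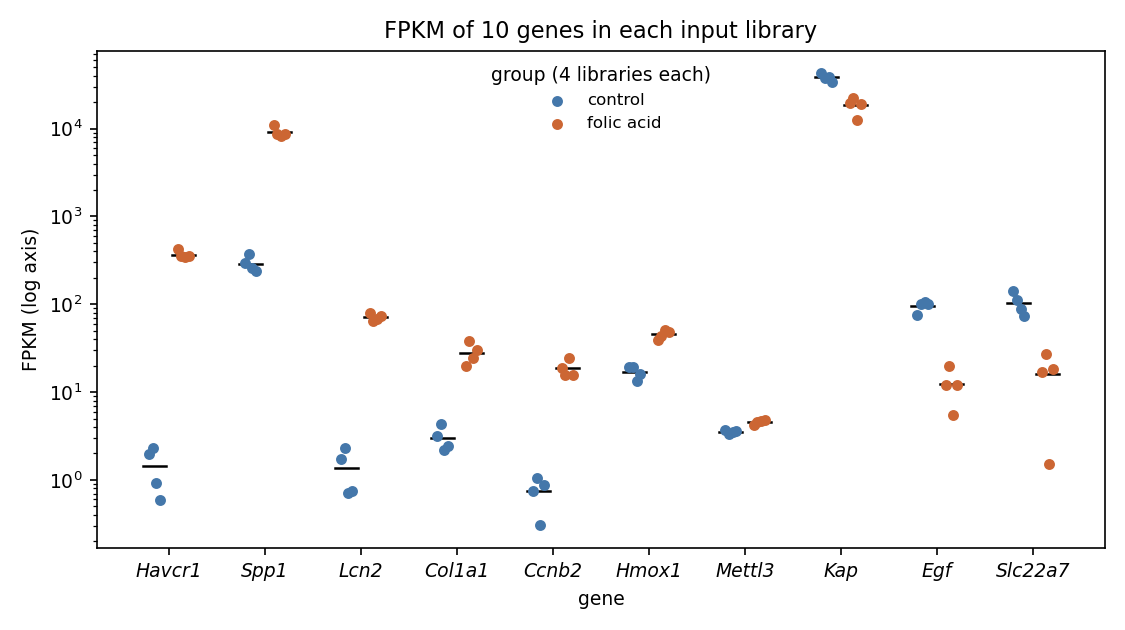
FPKM on a log axis (vertical) of 10 genes (horizontal) in each of the 4 control and 4 folic acid input libraries. Each point is 1 library and each bar the group mean; Havcr1 lies at 0.589 to 2.29 FPKM in control and 343 to 422 FPKM in folic acid libraries, and Kap at 33591 to 42642 and 12509 to 22171 FPKM.

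Transcripts of each listed tubule segment, from the proximal tubule to the collecting duct, were lower in FA kidneys, while the thin limbs had no list. In the proximal tubule list 41 of 44 genes fell, 1 rose and 2 did not pass the test. The list median was -0.95 relative to all genes (camera adjusted p = 3.1e-21, and adjusted p = 0.025 with an estimated correlation). The organic anion transporter gene Slc22a7 went from 104 ± 29.3 to 16.1 ± 10.7 FPKM (log2 difference -3.01 ± 0.65), with 1 FA library, replicate 3, at 1.53 FPKM. Hpd, of tyrosine breakdown, went from 24.1 ± 4.88 to 2.97 ± 0.959 FPKM (log2 difference -2.67 ± 0.18) and Cyp7b1 from 105 ± 23.5 to 25.1 ± 9.97 FPKM (log2 difference -2.10 ± 0.31). Kap fell from 38340.2 ± 3728 to 18372 ± 4122 FPKM (log2 difference -1.09 ± 0.18). It ranks highest in every library, so quantile normalization fixes its difference at 0, and without a filter on low values its limma adjusted p was 0.59. The sulfate transporter gene Slc13a1, named after its values were seen, was the member that rose, from 33.1 ± 1.85 to 82.2 ± 4.11 FPKM (log2 difference 1.29 ± 0.058).

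Of 12 thick ascending limb genes, 10 fell and 2 rose. Their relative median was -0.93 (camera adjusted p = 4.1e-05, and adjusted p = 0.30 with an estimated correlation). Egf went from 95.6 ± 13.2 to 12.4 ± 5.90 FPKM (log2 difference -2.96 ± 0.29) and Slc12a1, the sodium-potassium-chloride cotransporter gene, from 117 ± 15.3 to 41.5 ± 10.5 FPKM (log2 difference -1.498 ± 0.18). Umod, which encodes uromodulin, went from 1201 ± 198 to 811 ± 219.9 FPKM (log2 difference -0.60 ± 0.21), a call lost without control replicate 1, 2 or 3 (limma adjusted p = 0.053 to 0.080), without a filter on low values (0.099) and after quantile normalization (0.18). The claudin genes Cldn16 (0.44 ± 0.12) and Cldn19 (0.42 ± 0.13), named after their values were seen, rose with the deposited scaling but did not pass the test after quantile normalization or at the same 75th percentile. In the distal convoluted and connecting tubule 9 of 10 genes fell and 0 rose. Relative to all genes, the list median was -1.21 (camera adjusted p = 1.7e-06, and adjusted p = 0.20 with an estimated correlation). The thiazide-sensitive cotransporter gene Slc12a3 went from 80.9 ± 4.88 to 29.3 ± 5.49 FPKM (log2 difference -1.45 ± 0.12). The calcium-binding proteins' genes S100g and Pvalb went from 659 ± 103 to 169 ± 68.3 FPKM (log2 difference -2.04 ± 0.26) and from 10.3 ± 3.38 to 1.31 ± 0.517 FPKM (log2 difference -2.27 ± 0.22). All 11 intercalated cell genes fell, with a relative median of -0.995 (camera adjusted p = 1.7e-07, and adjusted p = 0.15 with an estimated correlation), among them the anion exchanger genes Slc4a1 (-1.74 ± 0.19) and Slc26a4 (-1.31 ± 0.18). Of 10 principal cell genes 6 fell and 2 rose. This gave a relative median of -0.67 (camera adjusted p = 0.0072, and adjusted p = 0.44 with an estimated correlation). This last call also ended after quantile normalization, with camera's adjusted p = 0.053. The water channel genes Aqp4 (-1.23 ± 0.16) and Aqp3 (-1.05 ± 0.17) fell, while St6gal1 (0.67 ± 0.12) and Fxyd4 (0.28 ± 0.066, named after its values were seen) rose. After quantile normalization or at the same 75th percentile Fxyd4 did not pass the test.

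Markers of cells other than the tubule moved in different directions. Matrix and fibroblast transcripts rose in 20 of 23 genes and fell in 0. The list median was 1.08 relative to all genes (camera adjusted p = 4.2e-05, and adjusted p = 0.44 with an estimated correlation). The collagen genes Col3a1 and Col1a1 rose from 2.59 ± 0.313 to 27.2 ± 8.20 FPKM (log2 difference 2.93 ± 0.18) and from 3.03 ± 0.984 to 28.0 ± 7.82 FPKM (log2 difference 2.84 ± 0.21). Macrophage and monocyte transcripts rose in 13 of 14 genes. Their relative median was 1.498 (camera adjusted p = 2.4e-05, and adjusted p = 0.25 with an estimated correlation). Cd14 rose from 1.53 ± 0.244 to 17.99 ± 2.90 FPKM (log2 difference 2.90 ± 0.12), the lysozyme gene Lyz2 from 17.1 ± 6.24 to 124 ± 27.4 FPKM (log2 difference 2.82 ± 0.24) and Cd68 from 3.54 ± 0.884 to 16.8 ± 0.935 FPKM (log2 difference 1.99 ± 0.12). The 3 neutrophil genes tested rose (S100a9 1.42 ± 0.39, S100a8 1.02 ± 0.22, Csf3r 0.88 ± 0.095), with a relative median of 0.87 and no call for the list (camera adjusted p = 0.18). Of 4 lymphocyte genes, Ighm rose (0.71 ± 0.12) and the others did not pass the test, Igkc at 35.9 ± 20.2 and 47.1 ± 14.7 FPKM (list median 0.16 relative to all genes, camera adjusted p = 0.84).

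Endothelial transcripts fell in 9 of 14 genes and rose in 1, against 10 and 1 adjusted over the list alone. Their relative median was -0.61 (camera adjusted p = 0.0017, and adjusted p = 0.44 with an estimated correlation), and with only genes of a mean of at least 5 FPKM tested camera's adjusted p was 0.0504. The fenestral diaphragm gene Plvap went from 56.2 ± 12.4 to 28.7 ± 7.80 FPKM (log2 difference -0.96 ± 0.20) and the VEGF receptor gene Kdr from 5.37 ± 1.84 to 2.37 ± 0.440 FPKM (log2 difference -0.88 ± 0.19). Plat, which encodes tissue plasminogen activator, was the member that rose, from 4.78 ± 1.28 to 19.7 ± 2.93 FPKM (log2 difference 1.85 ± 0.16). Podocyte genes went both ways: of 10 tested, 3 rose, 2 fell and 5 did not pass the test. Cdkn1c (0.46 ± 0.084) and Synpo (0.43 ± 0.10) were among those that rose, and Clic5 (-0.44 ± 0.074) among those that fell. Synpo and Clic5 were named after their values were seen, and Synpo did not pass the test after quantile normalization. The podocyte median was 0.045 with the deposited scaling and below 0 under quantile normalization, at the same 75th percentile and at the same total without the 50 most abundant genes, and -0.10 relative to all genes (camera direction lower, adjusted p = 0.50).

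All 6 red cell transcripts fell, with a relative median of -2.23 (camera adjusted p = 2.6e-05, and adjusted p = 0.053 with an estimated correlation); Slc4a1 belongs to this list and to the intercalated cell list. The globin genes Hbb-bs and Hba-a1 went from 28.1 ± 11.7 to 3.89 ± 1.04 FPKM (log2 difference -2.51 ± 0.27) and from 21.1 ± 9.11 to 3.64 ± 0.998 FPKM (log2 difference -2.18 ± 0.27). Lists for tissue that can adhere to the kidney had only 2 tested members each. Of the adipose genes, Cfd was listed at 0.240 to 6.06 FPKM in control and 0.321 to 12.2 FPKM in FA libraries and Fabp4 at 8.32 ± 1.34 and 7.61 ± 3.06 FPKM, and neither passed the test. Of the adrenal cortex genes, Fdx1 fell from 15.8 ± 1.25 to 13.2 ± 1.05 FPKM (log2 difference -0.24 ± 0.072) and Akr1b7, named after its values were seen, did not pass the test. Among 4 sex-linked genes tested, the Y-linked Eif2s3y rose from 11.2 ± 0.864 to 15.2 ± 0.746 FPKM (log2 difference 0.41 ± 0.064). Uty, Kdm5d and Ddx3y, named after their values were seen, did not pass the test. After quantile normalization 1 of the 4 was higher and 3 were lower. That list was not called (relative median -0.23, camera direction lower, adjusted p = 0.55), and its mean difference was 0.027 while its median was -0.086.

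Cytokine and chemokine transcripts rose in 15 of 16 genes and fell in 0, against 15 and 1 adjusted over the list alone. Relative to all genes, the list median was 2.27 (camera adjusted p = 2.0e-07, and adjusted p = 0.025 with an estimated correlation). The neutrophil-attracting chemokine gene Cxcl1 rose from 0.304 ± 0.171 to 24.1 ± 4.89 FPKM (log2 difference 4.26 ± 0.14) and the interferon-induced Cxcl10 rose from 1.34 ± 0.462 to 25.9 ± 4.51 FPKM (log2 difference 3.53 ± 0.16). Complement genes rose in 13 of 15 cases and fell in 1. This gave a relative median of 1.30 (camera adjusted p = 3.7e-04, and adjusted p = 0.051 with an estimated correlation). C3, the central complement component, rose from 2.98 ± 0.956 to 233 ± 41.6 FPKM (log2 difference 5.89 ± 0.18). Cfi and C4b rose from 1.23 ± 0.424 to 16.8 ± 2.46 FPKM (log2 difference 3.01 ± 0.14) and from 1.26 ± 0.447 to 7.80 ± 1.19 FPKM (log2 difference 1.97 ± 0.15). Cd55, a complement inhibitor named after its values were seen, fell from 4.05 ± 0.785 to 2.82 ± 0.437 FPKM (log2 difference -0.40 ± 0.12). Its call was lost without control replicate 1 or 2 or FA replicate 3 (limma adjusted p = 0.054 to 0.056) and without a filter on low values (limma adjusted p = 0.055).

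Cell cycle transcripts rose in 24 of 25 genes. The list median was 1.67 relative to all genes (camera adjusted p = 2.2e-09, and adjusted p = 0.25 with an estimated correlation). Ccnb2 and Cdc20, which act in mitosis, rose from 0.744 ± 0.318 to 18.7 ± 4.198 FPKM (log2 difference 3.50 ± 0.17) and from 0.680 ± 0.176 to 15.0 ± 4.58 FPKM (log2 difference 3.22 ± 0.17). The ribonucleotide reductase gene Rrm2 rose from 1.04 ± 0.228 to 14.3 ± 3.89 FPKM (log2 difference 2.88 ± 0.16), highest in FA replicate 3. Cyclin D1 (Ccnd1) was the member that fell, from 34.2 ± 6.12 to 25.9 ± 1.58 FPKM (log2 difference -0.37 ± 0.12). The Ccnd1 call was lost without control replicate 3 or 4 or FA replicate 1 (limma adjusted p = 0.052 to 0.058) and without a filter on low values (limma adjusted p = 0.057). Targets of p53 rose in 14 of 17 genes and fell in 0. Their relative median was 0.55 (camera adjusted p = 0.0017, and adjusted p = 0.23 with an estimated correlation). Gdf15 rose from 1.89 ± 0.547 to 19.6 ± 8.87 FPKM (log2 difference 2.76 ± 0.27) and the cell cycle inhibitor Cdkn1a from 1.05 ± 0.149 to 10.2 ± 1.28 FPKM (log2 difference 2.45 ± 0.090). Cell death genes rose in 15 of 20 cases (16 adjusted over the list alone) and fell in 0. Relative to all genes, the list median was 0.61 (camera adjusted p = 6.9e-04, and adjusted p = 0.051 with an estimated correlation). These included the apoptosis gene Pmaip1 (1.95 ± 0.057), Mlkl of necroptosis (1.33 ± 0.11) and Gsdmd of pyroptosis (1.31 ± 0.11).

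Genes of the ATF4 and unfolded protein response rose in 19 of 22 cases and fell in 0. This gave a relative median of 0.58 (camera adjusted p = 1.4e-04, and adjusted p = 0.053 with an estimated correlation). The transcription factor gene Atf3 rose from 0.435 ± 0.137 to 14.9 ± 3.43 FPKM (log2 difference 3.45 ± 0.14), and Asns and Phgdh, of asparagine and serine synthesis, rose from 1.63 ± 0.475 to 9.94 ± 1.71 FPKM (log2 difference 2.06 ± 0.14) and from 2.68 ± 0.599 to 13.04 ± 1.55 FPKM (log2 difference 1.94 ± 0.12). Immediate early genes, which can also rise during dissection, rose in 13 of 14 cases and fell in 0. The list median was 1.25 relative to all genes (camera adjusted p = 2.4e-05, and adjusted p = 0.25 with an estimated correlation). Klf6 rose from 4.06 ± 0.296 to 38.3 ± 2.85 FPKM (log2 difference 2.96 ± 0.069) and Junb from 5.95 ± 0.870 to 34.8 ± 2.31 FPKM (log2 difference 2.37 ± 0.092).

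Transcripts of mitochondrial and amino acid metabolism were lower in FA kidneys, while those of glycolysis and folate metabolism went both ways. Genes of fatty acid oxidation and its regulator PPARA fell in 18 of 30 cases and rose in 3. Their relative median was -0.46 (camera adjusted p = 1.8e-07, and adjusted p = 0.16 with an estimated correlation). The peroxisomal enzyme gene Ehhadh went from 254 ± 26.1 to 109 ± 17.2 FPKM (log2 difference -1.22 ± 0.12) and the acyl-CoA dehydrogenase gene Acadm from 211 ± 23.1 to 98.5 ± 14.0 FPKM (log2 difference -1.09 ± 0.11). Those that rose were Pdk4 (1.24 ± 0.22) and, named after their values were seen, Fabp1 (0.85 ± 0.13) and Slc25a20 (0.29 ± 0.072), of which Slc25a20 did not pass the test after quantile normalization or at the same 75th percentile. Pdk4 encodes an inhibitor of pyruvate oxidation, so its rise is not one of an oxidation enzyme. Genes of oxidative phosphorylation and the TCA cycle fell in 16 of 27 cases (17 adjusted over the list alone) and rose in 1. Relative to all genes, the list median was -0.47 (camera adjusted p = 2.0e-08, and adjusted p = 0.20 with an estimated correlation). Idh2 went from 186 ± 12.8 to 116 ± 2.76 FPKM (log2 difference -0.67 ± 0.060). The member that rose was Cox5a (0.30 ± 0.087, named after its values were seen), which did not pass the test at the same 75th percentile or at the same total without the 50 most abundant genes. Genes of gluconeogenesis and amino acid catabolism fell in 19 of 26 cases and rose in 1. This gave a relative median of -0.77 (camera adjusted p = 3.8e-11, and adjusted p = 0.051 with an estimated correlation). G6pc, whose product takes the last step of glucose release, went from 149.9 ± 26.5 to 63.0 ± 13.3 FPKM (log2 difference -1.24 ± 0.17).

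Glycolysis genes went both ways: 5 of 17 rose and 3 fell, against 4 and 6 after quantile normalization. Their median was 0.037 with the deposited scaling, below 0 under quantile normalization, at the same 75th percentile and at the same total without the 50 most abundant genes, and -0.11 relative to all genes (camera direction lower, adjusted p = 0.43). The hexokinase and phosphofructokinase isoforms split, with Hk2 (1.16 ± 0.070) and Pfkp (0.61 ± 0.11) higher and Hk1 (-0.34 ± 0.096) and Pfkm (-0.43 ± 0.12) lower. Pdk1 fell (-0.38 ± 0.080), and Slc2a1 (0.38 ± 0.11), Aldoa (0.23 ± 0.075) and Ldha (0.21 ± 0.066) rose with the deposited scaling. None of these 3 rises passed the test at the same 75th percentile or at the same total without the 50 most abundant genes. The Aldoa call was also lost without control replicate 3 or 4 or FA replicate 3 or 4 (limma adjusted p = 0.059 to 0.065) and without a filter on low values (0.060), and the Ldha call without control replicate 3 or FA replicate 3 or 4 (limma adjusted p = 0.050 to 0.054). Hk1, Pdk1, Slc2a1 and Ldha were named after their values were seen.

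Genes of folate uptake and one-carbon metabolism, the pathway of the injected compound, went both ways even within mitochondria. Of 20 tested, 7 rose and 9 fell, against 5 and 12 after quantile normalization. The mitochondrial enzyme genes Mthfd2 and Mthfd1l rose from 0.889 ± 0.301 to 4.59 ± 0.205 FPKM (log2 difference 1.58 ± 0.11) and from 0.267 ± 0.0609 to 2.18 ± 0.179 FPKM (log2 difference 1.33 ± 0.076). The thymidylate synthase gene Tyms rose from 1.76 ± 0.221 to 3.78 ± 0.681 FPKM (log2 difference 0.79 ± 0.10). Mthfd1, the cytosolic counterpart, went from 56.5 ± 1.51 to 30.1 ± 1.76 FPKM (log2 difference -0.89 ± 0.055). The mitochondrial serine hydroxymethyltransferase gene Shmt2 went from 81.6 ± 2.23 to 48.7 ± 0.957 FPKM (log2 difference -0.73 ± 0.045). The folate receptor gene Folr1 (-0.46 ± 0.069), the polyglutamate synthase gene Fpgs (-0.77 ± 0.062) and Aldh1l1 (-0.72 ± 0.081) also fell. The list had a relative median of -0.28 (camera adjusted p = 0.033, and adjusted p = 0.16 with an estimated correlation), and its mean difference was 0.016, of opposite sign to its median of -0.14. Its call ended after quantile normalization (camera adjusted p = 0.12), at the same 75th percentile (0.10), at the same total without the 50 most abundant genes (0.063) and without a filter on low values (0.10).

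Genes of iron handling and ferroptosis, an iron-dependent death by lipid peroxidation that the series title names, changed singly more than as groups when compared with other genes by camera. Fry, which does not compare a list with other genes, called these lists higher. Its adjusted p was 0.0018 for heme and iron, 8.9e-07 for ferroptosis drivers and 0.022 for ferroptosis defence. Of 19 heme and iron genes, 6 rose, 4 fell and 9 did not pass the test. After quantile normalization 5 were higher and 5 lower, and at the same 75th percentile 4 and 7. Besides Hmox1, the transferrin gene Trf rose from 3.70 ± 0.391 to 10.2 ± 1.28 FPKM (log2 difference 1.25 ± 0.097). The iron exporter gene Slc40a1 rose from 3.50 ± 0.524 to 5.81 ± 0.546 FPKM (log2 difference 0.60 ± 0.095). The importer gene Slc39a8 went from 7.85 ± 0.594 to 4.205 ± 0.416 FPKM (log2 difference -0.77 ± 0.075). The transferrin receptor gene Tfrc (-0.28 ± 0.081), Aco1 (-0.26 ± 0.060) and Ncoa4 (-0.30 ± 0.11), whose product delivers ferritin for breakdown, fell by less. The Ncoa4 call was lost without control replicate 3 or 4 or FA replicate 1 or 2 (limma adjusted p = 0.054 to 0.094), at the same total FPKM (0.066) and without a filter on low values (0.081). Fth1, which encodes ferritin heavy chain, had 1516 ± 142 and 1661 ± 84.3 FPKM and did not pass the test, although it was higher after quantile normalization (limma adjusted p = 0.0061). The heme and iron median was 0.10 with the deposited scaling, below 0 under quantile normalization and at the same 75th percentile, and -0.044 relative to all genes (camera direction lower, adjusted p = 0.59).

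Ferroptosis drivers rose in 7 of 12 genes and fell in 3, against 7 and 4 adjusted over the list alone (relative median 0.21, camera adjusted p = 0.50). Trp53 rose from 5.55 ± 0.433 to 13.7 ± 0.469 FPKM (log2 difference 1.17 ± 0.061), Sat1, of polyamine breakdown, from 63.8 ± 6.64 to 135 ± 5.22 FPKM (log2 difference 1.07 ± 0.076). Acsl4, which activates polyunsaturated fatty acids, rose from 5.17 ± 0.257 to 9.66 ± 1.002 FPKM (log2 difference 0.78 ± 0.076). Por, an electron donor to cytochromes P450, went from 106 ± 11.7 to 60.9 ± 3.18 FPKM (log2 difference -0.79 ± 0.080). Of 21 genes of ferroptosis defence and glutathione, 7 rose and 8 fell. The counts were 7 and 9 after quantile normalization, 4 and 10 at the same 75th percentile, and 4 and 9 at the same total without the 50 most abundant genes. The small heat shock protein gene Hspb1 rose from 5.51 ± 0.446 to 122 ± 13.7 FPKM (log2 difference 4.23 ± 0.086). Cbs, of cysteine synthesis, went from 28.8 ± 2.36 to 16.04 ± 0.368 FPKM (log2 difference -0.81 ± 0.063). Gpx3, the plasma glutathione peroxidase gene, fell from 11335 ± 879 to 8565 ± 678 FPKM (log2 difference -0.40 ± 0.10), a call lost without a filter on low values (limma adjusted p = 0.63). Gpx4, whose product reduces lipid peroxides, had 428 ± 38.6 and 465 ± 18.5 FPKM and did not pass the test, although it was higher after quantile normalization (limma adjusted p = 0.012). The defence list was not called (relative median -0.22, camera direction lower, adjusted p = 0.16). Its median of -0.070 turned positive under quantile normalization, and its mean was 0.18.

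Targets of the transcription factor NRF2 rose in 14 of 20 genes and fell in 3, with a relative median of 0.31 and no call for the list (camera adjusted p = 0.12). Camera called the list higher after quantile normalization (adjusted p = 0.0090), without a filter on low values (0.0062) and without FA replicate 2 (0.038). The glutathione transferase genes Gsta1 and Gsta2, close copies whose single values are uncertain, both passed the test: Gsta1 was listed at 0 to 3.25 FPKM in control and 9.37 to 17.3 FPKM in FA libraries, and Gsta2 rose from 85.0 ± 16.6 to 235 ± 51.0 FPKM (log2 difference 1.45 ± 0.18). The members that fell were Gclc (-0.46 ± 0.15) and, named after their values were seen, Me1 (-0.61 ± 0.055) and Osgin1 (-0.49 ± 0.17). Gclc missed the threshold without control replicate 1, 2 or 3 or FA replicate 1 or 3 (limma adjusted p = 0.055 to 0.063) and Osgin1 without control replicate 3 or 4 or FA replicate 1, 2 or 4 (0.051 to 0.093). Without a filter on low values both calls were lost as well (limma adjusted p = 0.069 and 0.092).

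Transcripts of renal hormones and mineral handling fell in 8 of 14 genes and rose in 4. The list median was -0.59 relative to all genes (camera adjusted p = 0.0038, and adjusted p = 0.17 with an estimated correlation). After quantile normalization the list was not called (camera adjusted p = 0.076). Kl, which encodes the FGF23 co-receptor klotho, went from 63.9 ± 2.10 to 25.8 ± 3.42 FPKM (log2 difference -1.28 ± 0.088), and Dnase1 from 223 ± 60.7 to 46.4 ± 7.75 FPKM (log2 difference -2.21 ± 0.19). Among the members that rose, and named after their values were seen, were Cyp27b1 (1.19 ± 0.19), which activates vitamin D, the prostaglandin D synthase gene Ptgds (0.97 ± 0.15) and the angiotensinogen gene Agt (0.61 ± 0.14).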

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

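Each named gene's 4 control and 4 FA libraries were checked for 1 library far from the other 3, by the gap to the nearest library as a share of the group's range (Dixon's test). Of 274 groups of 4 libraries, 25 held such a library, where chance gives about 1 in 20. FA replicate 3 was the library in 9 of them, more than any other library. It was the highest of its group for Rrm2 (20.1 against 11.9 to 13.1 FPKM), Cdkn1a (12.1 against 9.47 to 9.82 FPKM), Shmt2 (50.1 against 48.1 to 48.3 FPKM), Tyms (4.80 against 3.36 to 3.51 FPKM), Cxcl1 (31.5 against 21.6 to 21.8 FPKM) and Igf2bp2 (2.16 against 1.74 to 1.80 FPKM). In the same library the lowest values of the group were those of Mthfd2 (4.29 against 4.69 to 4.70 FPKM), Cyp27b1 (2.505 against 4.13 to 4.26 FPKM) and Ehhadh (83.9 against 116 to 120.4 FPKM).

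Other libraries stood apart for fewer genes, and no explanation was tested for any of these values. FA replicate 1 stood above the other 3 for Spp1 (11134 against 8252 to 8651 FPKM), Slc25a20 (11.5 against 10.7 to 10.8 FPKM) and Havcr1 (422 against 343 to 354 FPKM). FA replicate 2 stood above the other 3 for Pvalb (2.08 against 0.973 to 1.16 FPKM), Gsdmd (7.56 against 5.53 to 5.79 FPKM) and Atf3 (20.01 against 12.6 to 13.6 FPKM). FA replicate 4 stood above the other 3 for Por (65.6 against 58.9 to 59.9 FPKM) and below them for Alkbh5 (15.1 against 15.98 to 16.1 FPKM). Control replicate 1 stood below the other 3 for Egf (76.1 against 100.3 to 105 FPKM) and Elavl1 (4.39 against 4.80 to 4.86 FPKM). Control replicate 2 stood above the other 3 for Pfkm (17.9 against 14.5 to 15.0 FPKM). Control replicate 3 stood above the other 3 for Fdx1 (17.7 against 15.0 to 15.4 FPKM) and Hba-a2 (27.0 against 14.3 to 16.1 FPKM). Control replicate 4 stood above the other 3 for Igf2bp2 (0.963 against 0.525 to 0.594 FPKM), Ncoa4 (10.7 against 8.04 to 8.42 FPKM) and Cfd (6.06 against 0.240 to 0.510 FPKM).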

How the results depend on the processing

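Chosen after seeing the data were the scaling to the same total without the 50 most abundant genes and the leave-one-out comparison with the genes tested held fixed. Hmox1 kept its direction and its side of the threshold under every alternative run (log2 difference 1.17 to 1.44). Mettl3 fell short of the threshold after quantile normalization (0.091) and at the same 75th percentile (0.14), and kept its call in the other alternatives, with limma adjusted p between 0.0015 and 0.19 over all. Quantile normalization gave 3364 genes higher and 4265 lower, and 333 at least 2-fold lower; the same 75th percentile gave 3614, 3855 and 339. Both align the libraries with each other, which by construction takes out most of a shared shift. Of the 5487 genes higher with deposited values 3361 kept their call under quantile normalization, and of the 2300 lower 2292 did. With a mean of at least 5 FPKM, which tests 7019 genes, 4685 passed, 3093 of them higher, and 473 were at least 2-fold higher. Leaving out each library in turn gave 6695 to 7466 genes, 630 to 932 at least 2-fold higher and 177 to 239 at least 2-fold lower; with the genes tested held fixed these were 7214 to 7526, 886 to 955 and 177 to 241. Of the lists called higher, an estimated correlation left 2 and of those called lower 1, while fry, which does not compare a list with other genes, called 17 higher and 9 lower, without principal cell (0.072), endothelium (0.18) and folate handling (0.19, all fry adjusted p). Called higher by fry but not by camera were both m6A lists, heme and iron, both ferroptosis lists, NRF2 targets and neutrophil. For heme and iron and for ferroptosis defence the direction by camera was lower. Mettl14 reversed under quantile normalization (-0.0029, not past the threshold there). Among 137 named genes, calls ended for 14 (Mettl14 among them) under quantile normalization, 14 at the same 75th percentile, 8 without the 50 most abundant genes, 9 without a filter, 1 at the same total and 8 when some library was left out. Calls arose for 4 (Fth1, Gpx4, Fto, Alkbh5) under quantile normalization, for Fto and Alkbh5 at the same 75th percentile, for Fto without the 50 most abundant genes, and on leaving out control replicate 1 for Igkc (0.035) and FA replicate 2 for Fabp4 (0.048, both limma adjusted p). A pseudocount of 0.1 gave 1366 genes at least 2-fold higher and 320 lower. The pseudocount, array weights and the robust fit changed no named gene's call. Where no construction is given, the cause was not tested. The replicate numbers do not pair the libraries: same-numbered control and FA libraries had correlations of deviations from -0.042 to 0.074, and with the number as a block 7516 genes passed, no list call changed, and of the named genes Aldoa alone lost its call (limma adjusted p = 0.062). Not run were the alternatives for the m6A-selected libraries, those that need read counts (edgeR and DESeq2), and all groups of libraries in 1 fit.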

Other observations

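Tests in this part were chosen after the results they bear on had been seen, apart from those set beforehand and repeated here. The latter are the limma comparison, the scalings set beforehand, and the camera calls of the fixed lists, with and without an estimated correlation. Their use on pathways and on ribosomal protein gene families was chosen afterwards. Pathways as the authors' table assigns them (KEGG, 300 with at least 10 tested genes) were put through camera, which called 80 higher and 46 lower in FA kidneys. With an estimated correlation 0 higher and 2 lower calls were left. Breakdown of branched-chain amino acids led the lower pathways: of 44 genes 38 fell and 0 rose (camera adjusted p = 2.8e-17, and adjusted p = 0.088 with an estimated correlation). Glyoxylate and dicarboxylate metabolism (23 of 27 genes fell) and tryptophan metabolism (25 of 30 fell and 3 rose) kept their calls with an estimated correlation, at a camera adjusted p of 0.045 for each. Higher pathways included DNA replication (30 of 32 genes rose, camera adjusted p = 8.1e-06, and adjusted p = 0.40 with an estimated correlation) and the spliceosome (91 of 127 rose and 2 fell, camera adjusted p = 4.3e-05, and adjusted p = 0.18 with an estimated correlation).

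The ribosome pathway was also higher, with 105 of 131 genes up and 6 down (camera adjusted p = 6.1e-08, and adjusted p = 0.55 with an estimated correlation). Genes of cytosolic ribosomal proteins were taken by symbol (Rpl or Rps followed by a number), which leaves out other symbol forms and includes paralogs such as Rpl7l1 and Rpl22l1. They rose in 76 of 77 cases, and in 68 at the same 75th percentile, with a median 0.56 above that of all genes. Among them Rps15 went from 622 ± 72.6 to 835 ± 50.1 FPKM (SD, n = 4) and Rpl8 from 261 ± 18.7 to 333 ± 16.9 FPKM (SD, n = 4). Rpl3l, a muscle paralog, was the member that fell, from 2.31 ± 0.491 to 0.789 ± 0.329 FPKM (SD, n = 4). Genes of mitochondrial ribosomal proteins went both ways, with 29 of 78 higher and 7 lower. The balance turned over under quantile normalization (10 higher and 25 lower) and at the same 75th percentile (11 and 28), and their median of 0.10 turned negative under quantile normalization and at the same 75th percentile. Ribosomal protein genes have many near-identical pseudogenes, so single values are uncertain.

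The number of genes that differed between FA and control kidneys was set against all 35 splits of the 8 libraries into 4 and 4. Only 1, the real split, gave as many as 7787 genes past the threshold, and the highest of the others gave 2. Every other split puts FA and control libraries on both sides, which widens the spread within each side. Few calls there follow from the separation of the groups already seen, so no further conclusion is drawn.

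More genes were higher than lower in FA kidneys with the deposited scaling (70.5% of calls) but not under quantile normalization (44.1%). A candidate explanation is that Kap and other abundant transcripts took a smaller share of the summed FPKM; the 50 most abundant genes held 29.8% ± 0.801 in controls and 23.6% ± 1.48 in FA kidneys (SD, n = 4). With those genes left out of the total, the median difference was 0.063 (0.055 to 0.085 over leaving out each library), 42.6% of the deposited value. This argues against these 50 genes as the whole cause and leaves them as part of it. The cut at 50 was chosen after the data were seen and no other cut was run. Abundant transcripts beyond these 50 therefore stay open as the rest of the cause. Total FPKM averaged 303199 ± 8845 in controls and 299624 ± 2645 in FA kidneys (SD, n = 4), with overlapping ranges. On average, unequal totals thus act against the shift rather than for it. The median of 0.16 at the same total follows from these totals and is no separate test. Whether a kidney held more mRNA after FA was not measured, so the direction of the remaining shift stays open.

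Markers of each tubule segment that had a list were lower in FA kidneys. Of these lists, however, only the proximal tubule kept its camera call with an estimated correlation, and the principal cell call also ended after quantile normalization. A loss of proximal tubule cells alone would raise the share of other segments, yet the 43 distal segment markers had a median difference of -0.77 (95% bootstrap interval over genes -0.98 to -0.61; medians of single libraries against the control mean, FA -1.19 to -0.59 and control -0.062 to 0.080, exact permutation p = 0.0286), which argues against it as the whole cause. An equal dilution of all resident cells would lower podocyte markers by as much, but the podocyte median lay 0.82 above the distal median (0.44 to 1.27 over genes; 0.49 to 1.31 in single FA libraries, exact permutation p = 0.0286), which argues against a dilution alike for all. Endothelial markers fell in 9 of 14 genes, but their medians in single libraries overlapped (FA -0.74 to -0.092 and control -0.26 to 0.29, exact permutation p = 0.086). Their distance from the distal median was -0.095 to 0.69 in FA and -0.34 to 0.27 in control libraries (exact permutation p = 0.143). A dilution that spared podocytes therefore stays open. Lower expression within surviving tubule cells and a loss of cells in several segments may each be part of it; neither was tested.

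Cytosolic ribosomal protein genes are short and abundant, and differences fell with gene span over protein-coding genes, so their rise could follow such a trend. Their median of 0.71 lay above all 10000 random lists matched on span and expression (-0.20 to 0.32, median 0.044). Matched genes thus did not typically rise as much. The lists drew genes independently, so their range is too narrow for genes that move together, and the closeness of the match was not checked. Whether a trend with gene span and level is the whole cause is therefore not settled. If reads moved from pseudogene copies to the parent genes were the whole cause, the pseudogenes would fall. Yet the 126 ribosomal protein pseudogenes had a median of 0.55 (0.52 to 0.67). Values of near-identical copies can rise with those of the parent genes, so a part played by moved reads stays open. Transcript length, RNA integrity and a coordinated rise of ribosomal protein mRNA after FA stay open, the last as a hypothesis.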
